A study of Homo sapiens with 48 samples.

How the data were processed

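RNA was sequenced from 48 cultures of the human embryonic stem cell line H9, in 24 groups of 2. Per the labels' protocols, cells grew as a monolayer in E6 medium and differentiated for 8 days while exposed to test compounds or their metabolites, with 2 replicates per exposure. One group was taken on day 0 and the other 23 on day 8. Per the labels' protocols, mRNA was enriched with oligo-dT, fragmented, primed with random hexamers, made into a circular DNA library and sequenced on an MGI instrument. Whether the library kept strand is not stated, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain as well.

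The labels name 3 compound families as NEOs, OPEs and SPAs and do not say which compound belongs to which. TDCIPP, TEP and TPHP are organophosphate esters, and BHT, BHA and TBHQ are phenolic antioxidants, from general knowledge. ACE, CYC and IMI were placed with the NEO family, and AO168_O, AO_2246, DG and DTBP with the SPA family, as an assumption from their abbreviations that the labels do not settle. BHT_CHO and BHT_COOH were read as the aldehyde and acid forms of BHT. Doses, culture batches and the meaning of S9 are not given in the labels. In toxicology, S9 commonly names a liver fraction added to metabolise a test compound.

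The deposited table held 19253 genes with a symbol each. Expected counts (read counts with decimals) were deposited for each library per the file headers. The aligner, the counting tool and their versions are not given in the sources used here. The reads were mapped to GRCh38.p13 per the submitters' processing notes. The authors also deposited TPM values, which summed to the same total in every library, and FPKM values, which were proportional to TPM within a library. The authors' log2 fold changes were deposited for pairs of groups and were made with DESeq2 per the file headers, with no version stated. The authors' p-value and q-value columns were deposited beside them, per the file headers from DESeq2. That part of the table ended inside the comparison of IMI with DMSO, so the remaining pairs are not used here. TPM and FPKM were used for no test.

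All other values were computed from the expected counts, rounded to whole numbers, which changed 43.4% of the values. Library totals ran from 17918867 to 20096130 counts, and 17066 to 17992 genes had a count. The 10 most abundant genes took 5.42% to 7.37% of a library. A count of 0 in a library allowed up to 3 counts. Such limits and the intervals of counts cover counting error only. CPM (counts relative to the library total) were scaled with TMM factors, which lay between 0.848 and 1.05. A mean CPM is given with its standard deviation (SD) over the 2 libraries of a group.

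Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM, glmQLFit and glmQLFTest, 1 coefficient per group). Benjamini-Hochberg adjustment was made per comparison, and an adjusted p under 0.05 counted as changed. Each log2 fold change is given with its standard error (SE). Compounds and S9 were tested in a fit of the 46 libraries of day 8, with 16113 genes and 23 residual degrees of freedom. DMSO was compared with day 0 in a fit of all 48 libraries, with 16209 genes and 24 residual degrees of freedom. The average effect of S9 was tested in the 28 libraries of the 7 treatments with and without S9, with treatment and S9 as terms, 15982 genes and 20 residual degrees of freedom. The common biological coefficient of variation was 12.5% in the day 8 fit. The spread is shared over all groups because 2 libraries per group give little of their own. The p-values therefore measure the spread between libraries, and the labels do not say how far 2 replicates of a group were independent cultures. Replicates were not equally close: their median chi-square was 1.86 times that of counting error in DMSO_S9, 11.8 times in AO_2246 and 12 times in TBHQ. A shared spread can thus be too small for some groups and too large for others.

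Genes were named by a rule: adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean CPM of at least 1 in the higher group and no overlap between the libraries of both groups. Genes were ranked by p, with up to 10 each way for day 8 against day 0, 8 each way for S9, 4 each way for each compound and 3 each way for interactions and compound pairs. The 10 genes changed alike in the most compounds and the members of 26 fixed gene lists were added. Of these lists, 25 had at least 3 genes measured. List tests used camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over 600 tests of 25 lists in 24 comparisons. In this family, 102 tests passed with the preset correlation and 1 passed with a correlation estimated from the data, cholesterol synthesis in DMSO against day 0. Tests, lists and the naming rule were fixed before the data were examined.

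On simulated counts with BHT and DMSO sizes (16077 genes), the test recovered 35 of 50 genes raised by a log2 change of 1 and 44 of 50 raised by 2, with 3 false calls among 15877 unchanged genes. On counts simulated for S9 across 7 treatments (15851 genes), it recovered 48 of 50 and 50 of 50, with 6 false calls among 15651. A simulated list raised by 1 on the log2 scale in BHT against DMSO (16082 genes) reached an adjusted p of 3.54e-42, and 0 of the 24 other lists passed with camera. Each gene was drawn independently in these counts, with no trend of GC content or batch between libraries. The numbers of false calls thus do not cover such trends.

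Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, fits of only the groups compared, leaving out each library in turn, a replicate block and other references. After the data had been seen, 5 more were added, among them offsets for GC content and transcript length (mgcv 1.9.3). Gene properties came from a RefSeq table that matched 19079 of the genes. That table follows another assembly version, so no coordinates are given. In a check for mixed-up samples, 2 libraries did not match the labels, and the level limit of that check was set after its values were seen. All 48 libraries were kept under their labels in the main fits.

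The ectoderm score of a library was the mean log2(CPM + 1) of the surface ectoderm list minus that of the neural ectoderm list. It was compared with exact permutation tests. For the overlap of compounds that share the DMSO libraries, unchanged groups were simulated 5 times against those libraries, with each gene drawn independently. The 2 DMSO libraries could not be divided into parts with replicates.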

Results

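The data were expected read counts per gene in 48 libraries of H9 human embryonic stem cells, 2 libraries in each of 24 groups. The group D0 was taken on day 0. All other groups were taken after 8 days of differentiation in E6 medium. DMSO was the solvent control and DMSO_S9 the solvent control with S9. The test compounds were placed, by assumption from their names, as 9 of the SPA family (AO168_O, AO_2246, BHA, BHT, BHT_CHO, BHT_COOH, DG, DTBP and TBHQ), 3 of the NEO family (ACE, CYC and IMI) and 3 of the OPE family (TDCIPP, TEP and TPHP). The last 6 were also given with S9. Library totals ran from 17918867 to 20096130 counts. Values below are means over 2 libraries per group, with SD for CPM and SE for log2 fold changes, and adjusted p-values come from the edgeR quasi-likelihood test. Doses are not given in the labels, so differences between compounds are differences between the exposures used.

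The first comparison asked what 8 days of differentiation with solvent did to the cells. Genes of the undifferentiated state fell: POU5F1 went from 3152 ± 308 CPM on D0 to 698 ± 246 CPM in DMSO (log2 fold change -2.18, SE 0.38, adjusted p 1.82e-05), and NODAL fell from 76.4 ± 8.97 to 0.894 ± 0.326 CPM. NANOG fell as well (log2 fold change -1.51, SE 0.34, adjusted p 0.000369), whereas SOX2, which neural progenitors also express, rose by 0.57 on the log2 scale (SE 0.20, adjusted p 0.0168), a call lost without D0 replicate 2 (0.47) or DMSO replicate 1 (0.51). Genes of the anterior neural ectoderm rose, among them LHX5 (1.61 ± 0.204 to 350 ± 0.181 CPM; log2 fold change 7.76, SE 0.42, adjusted p 1.09e-14), SIX3 (7.88, SE 0.79) and PAX6 (5.70, SE 1.24). Genes of the placode and surface ectoderm rose beside them, with DLX5 at a log2 fold change of 8.03 (SE 0.97) and GATA3 at 3.73 (SE 0.76). Further genes that rose were CRABP2, a carrier of retinoic acid (78.5 ± 12.6 to 742 ± 3.6 CPM), CYP26A1, which degrades it (log2 fold change 5.96, SE 0.36), FIGNL2 (2.86, SE 0.13, adjusted p 8.16e-16), BST2, CITED2, MSI2 and HRC. Lower on day 8 were NOP16 (log2 fold change -2.10, SE 0.10, adjusted p 8.16e-16), SLC38A5 (-3.06, SE 0.14), PES1, EBNA1BP2 and PSME3. Enzymes of sterol synthesis fell together, with ACAT2 at -3.50 (SE 0.20, adjusted p 2.14e-14), MVD at -2.83 (SE 0.16), DHCR7 at -2.03 (SE 0.11), NSDHL at -1.95 (SE 0.09) and CYP51A1 at -1.85 (SE 0.09).

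Across the fixed lists, cholesterol synthesis stood out in DMSO against D0: 20 of 20 genes fell, the same 20 when adjusted over the list alone (camera adjusted p 5.21e-25, and adjusted p = 0.00342 with an estimated correlation). Of 20 pluripotency genes, 15 fell and 2 rose (camera adjusted p 0.00024, adjusted p = 0.858 with an estimated correlation), with the same counts adjusted over the list alone. Neural ectoderm genes went the other way, with 13 of 22 higher and 2 lower (camera adjusted p 0.000438, adjusted p = 0.858 with an estimated correlation). In the surface ectoderm list 8 of 15 genes rose and 1 fell (camera adjusted p 0.0271, adjusted p = 0.905 with an estimated correlation). Targets of NRF2, the regulator of antioxidant defence, were lower for 15 of 24 genes and higher for 2 (camera adjusted p 0.000203, adjusted p = 0.518 with an estimated correlation), led by HMOX1 (log2 fold change -3.43, SE 0.27) and NQO1 (-2.47, SE 0.18). Retinoic acid targets had 5 of 13 genes higher and 2 lower (camera adjusted p 0.0204, adjusted p = 0.518 with an estimated correlation). Of 8 metallothioneins measured, 7 fell (camera adjusted p 0.0523), for example MT1X by 2.02 on the log2 scale (SE 0.34). In all, 9434 of 16209 genes changed, 4724 higher and 4710 lower, and 3997 of them changed at least 2-fold. Both D0 libraries and both DMSO libraries entered this count, which lay between 7971 and 8735 when any 1 of them was left out.

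The next comparisons asked how the NEO and OPE compounds without S9 changed day 8 cells relative to DMSO. The same ectodermal genes moved in all 6. GATA3, a regulator of surface ectoderm and trophoblast, rose from 21.9 ± 4.47 CPM in DMSO to 466 ± 35.5 CPM in CYC (log2 fold change 4.41, SE 0.61, adjusted p 2.09e-05), and its log2 fold changes in the other 5 compounds ran from 3.52 in IMI to 3.85 in TEP. HAND1, expressed in amnion and extraembryonic mesoderm, went from 0.332 ± 0.181 to 102 ± 41.8 CPM in CYC (log2 fold change 8.23, SE 1.40, adjusted p 0.000107) and rose by 5.73 in IMI to 7.37 in TPHP on the log2 scale. TFAP2A rose by 3.55 in IMI to 4.70 in CYC and ISL1 by 5.30 in IMI to 6.85 in CYC on the log2 scale. The simple-epithelium keratin KRT8 went from 889 ± 6.81 CPM in DMSO to 3258 ± 81.2 CPM in CYC (log2 fold change 1.87, SE 0.29), with 1.45 in IMI at the low end. Feedback targets of BMP signalling rose with them: BAMBI by 2.95 in IMI to 3.95 in CYC, ID1 by 0.82 in ACE to 1.39 in TPHP and BMP4 itself by 1.52 in TDCIPP to 2.05 in TEP. SPHK1, a lipid kinase, ranked among the first genes by p in all 6 comparisons, with log2 fold changes between 2.04 in ACE and 2.59 in CYC (SE 0.28 each), and passed in each of these comparisons whichever library was left out. RARB rose by 2.60 in TEP to 3.27 in CYC on the log2 scale.

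SOX2, ZIC1 and STMN2 went down in the same 6 groups, while SIX3 and PAX6 passed in fewer. SOX2 fell by 0.82 in TDCIPP to 1.54 in CYC on the log2 scale, from 555 ± 30.2 CPM in DMSO to 191 ± 27.2 CPM in CYC. ZIC1, a neural plate gene at 5.16 ± 2.74 CPM in DMSO, was at 0.48 ± 0.0439 CPM in CYC (log2 fold change -3.41, SE 0.79, adjusted p 0.00187) and fell in the other 5 as well, by 2.49 in TDCIPP to 3.81 in TEP. SIX3 fell in 4 of the 6, with -2.95 in CYC (SE 0.58, adjusted p 0.000439). The SIX3 call was lost in IMI whichever library was left out (-1.43 to -2.23), without TEP replicate 1 in TEP (-2.33) and without TPHP replicate 1 (-1.49) or DMSO replicate 2 in TPHP. In ACE (-1.71, adjusted p 0.0507) and TDCIPP (-1.35, adjusted p 0.118) SIX3 did not pass. PAX6 passed in CYC alone (-2.94, SE 0.95, adjusted p 0.0195), where the call was lost without CYC replicate 1, CYC replicate 2 or DMSO replicate 2, and not in the other 5 (-1.74 in ACE to -2.71 in TEP, adjusted p 0.0527 to 0.219). STMN2, a marker of young neurons, fell in all 6, with log2 fold changes of -2.82 in IMI to -4.27 in CYC. PTN, ETV1 and LRRC20 fell in all 6 too, LRRC20 by 1.15 in ACE to 1.91 in CYC on the log2 scale. POU5F1 passed in none of the 6 (edgeR adjusted p 0.227 to 0.863), and NANOG passed in CYC alone (log2 fold change -1.58, SE 0.36, adjusted p 0.00177).

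**Figure D1:**
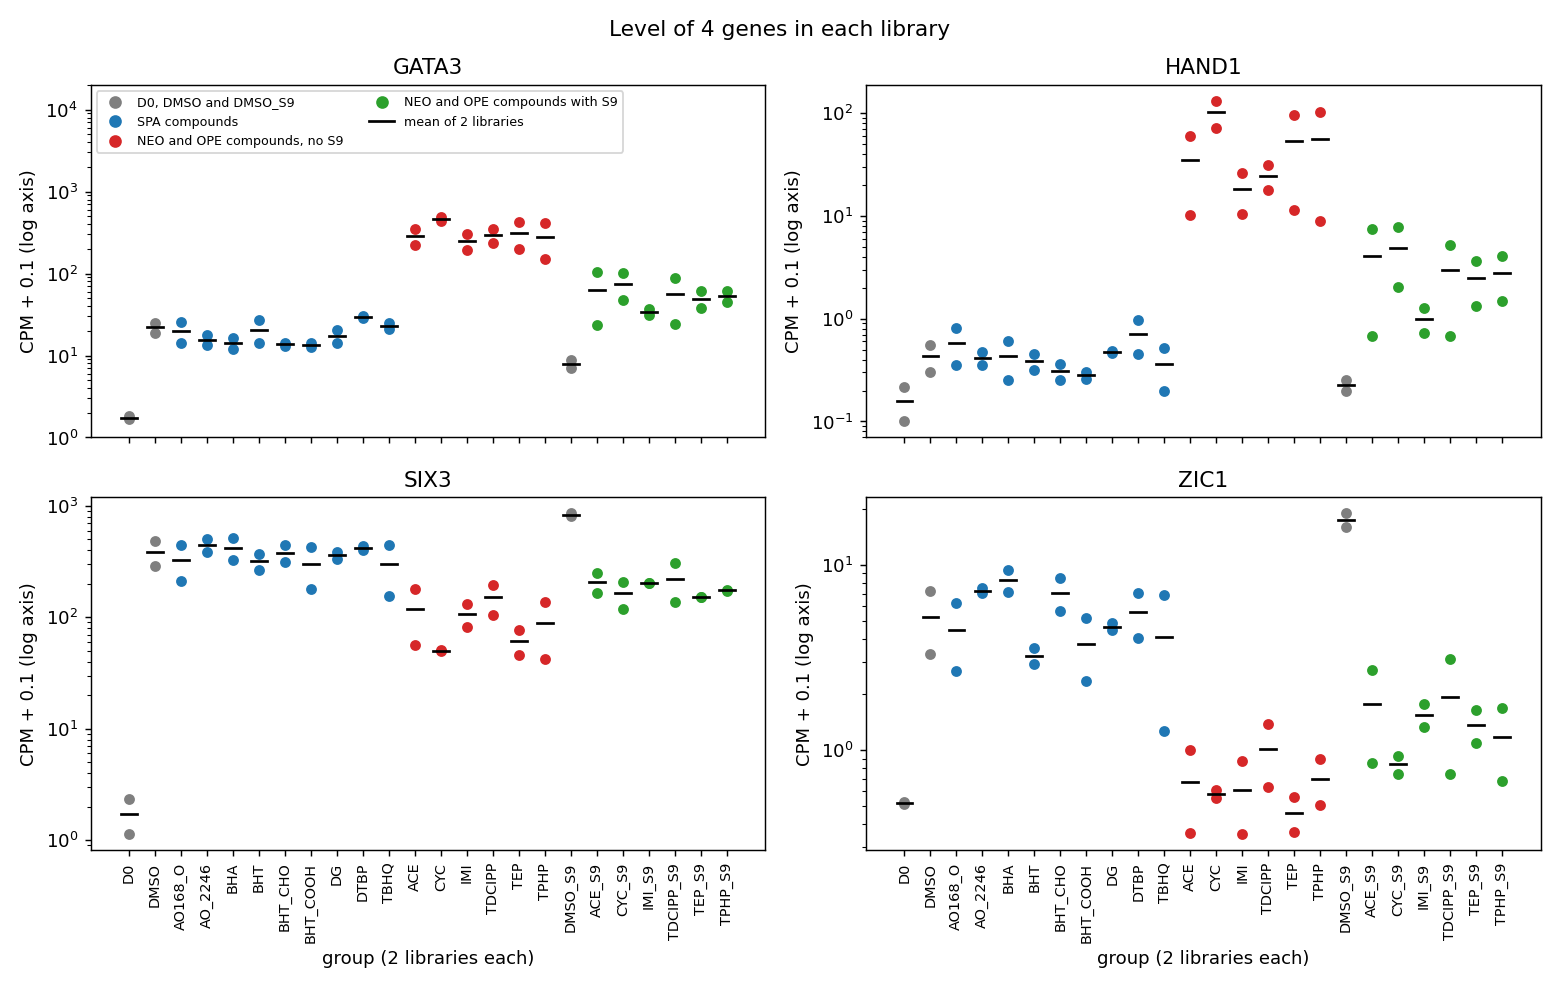
Expression of GATA3, HAND1, SIX3 and ZIC1 as CPM + 0.1 on a log axis, 1 point per library, with groups along the horizontal axis and 2 libraries per group. GATA3 was at 21.9 CPM in DMSO and 466 CPM in CYC, and ZIC1 at 5.16 and 0.48 CPM.

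Gene lists summarised these shifts. Of 15 surface ectoderm genes, 9 rose in ACE, 12 in CYC, 7 in IMI, 8 in TDCIPP, 11 in TEP and 10 in TPHP, and adjusted over the list alone 11, 12, 11, 10, 11 and 11 (camera adjusted p 9.51e-11 to 4.68e-09, adjusted p = 0.518 to 0.562 with an estimated correlation). Of 14 BMP and TGF-beta targets, 8, 9, 8, 7, 10 and 10 rose in the same order, 2 also fell in CYC, and adjusted over the list alone 9, 9, 10, 10, 10 and 10 rose (camera adjusted p 8.49e-09 to 1.64e-05, adjusted p = 0.518 to 0.586 with an estimated correlation). Amnion and trophoblast genes rose in part, with 7 of 12 in CYC and 3 of 12 in IMI (camera adjusted p 0.000671 to 0.0204, adjusted p = 0.747 to 0.833 with an estimated correlation). Of 22 neural ectoderm genes, 4, 13, 6, 2, 9 and 7 fell in the same order, 1 rose in ACE and in CYC, and adjusted over the list alone 8, 14, 8, 3, 13 and 10 fell (camera adjusted p 1.44e-07 to 0.00294 over the 6, adjusted p = 0.747 to 0.904 with an estimated correlation). Pluripotency genes fell in part, 11 of 18 in CYC and 2 in ACE (camera adjusted p 1.66e-05 to 0.0175 over the 6, adjusted p = 0.817 to 0.996 with an estimated correlation). None of these list calls held with an estimated correlation.

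In CYC, genes of sterol synthesis and of the nicotinic receptors were counted as well. Of 20 cholesterol synthesis genes 10 fell in CYC, among them HMGCS1 by 0.53 on the log2 scale (camera adjusted p 0.00344, adjusted p = 0.817 with an estimated correlation). HMGCS1 did not pass without CYC replicate 1 (-0.47) or DMSO replicate 1 (-0.45). Of 11 nicotinic receptor genes, 4 fell in CYC, with CHRNB4 at a log2 fold change of -2.02 (SE 0.51, adjusted p 0.00405) and CHRNA3 also lower (SE 0.40, adjusted p 0.00594), while 1 fell in ACE and 0 passed in IMI by edgeR. Without CYC replicate 1 neither CHRNB4 (-1.77) nor CHRNA3 (-1.32) passed, and CHRNA3 did not without DMSO replicate 2 (-1.15). As a list, the nicotinic receptors passed in none of these 3 (camera adjusted p 0.182 in CYC and 0.303 in ACE). CYC was tested directly against ACE and IMI alone, as given below for pairs of compounds.

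In CYC, GATA3, HAND1, KRT8, SIX3, ZIC1 and SOX2 passed whichever library was left out, and GATA3 did so in all 6 compounds. HAND1 did not pass in ACE without ACE replicate 2 (4.90), IMI without IMI replicate 2 (4.92), TDCIPP without TDCIPP replicate 2 (5.73), TEP without TEP replicate 1 (5.05) or TPHP without TPHP replicate 1 (4.71). SOX2 was lost without the same libraries (-0.82, -0.73, -0.69, -0.63 and -0.64 in that order), as were KRT8, ZIC1 and RARB. ISL1, TFAP2A, BAMBI, BMP4 and STMN2 were lost without them in ACE, IMI, TDCIPP and TPHP, and ID1 and LRRC20 in ACE, IMI and TDCIPP. Without DMSO replicate 1, HAND1, KRT8, BMP4 and SOX2 were lost in ACE, IMI and TDCIPP, ISL1, TFAP2A and STMN2 in IMI and TDCIPP, BAMBI and RARB in IMI, ID1 in ACE and ZIC1 in TDCIPP. ZIC1 was also lost without IMI replicate 1 in IMI and without DMSO replicate 2 in ACE, IMI, TDCIPP and TPHP, HAND1 and ISL1 without it in IMI, ID1 without it in ACE, and RARB without it in IMI, TDCIPP, TEP and TPHP. Numbers of changed genes against DMSO were 1378 in ACE (798 higher, 580 lower), 4762 in CYC (2316 and 2446), 1001 in IMI (560 and 441), 1460 in TDCIPP (887 and 573), 2041 in TEP (1092 and 949) and 1826 in TPHP (1048 and 778). Changes of at least 2-fold numbered 466, 1506, 327, 376, 698 and 542 in that order. The counts depended on single libraries. Without DMSO replicate 1 they were 148, 2398, 94, 107, 605 and 400. Without ACE replicate 2 the count for ACE was 18, and without IMI replicate 2 that for IMI was 19 (590 without IMI replicate 1). Without CYC replicate 1 or 2, CYC had 2790 and 3071 genes. Without TDCIPP replicate 2, TEP replicate 1 and TPHP replicate 1 the counts for these compounds were 34, 206 and 79. The authors' deposited table gave 703 genes with a q-value under 0.05 for ACE and 3259 for CYC, and its log2 fold changes had a Pearson correlation across genes of 0.996 and 0.998 with those computed here.

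**Figure D2:**
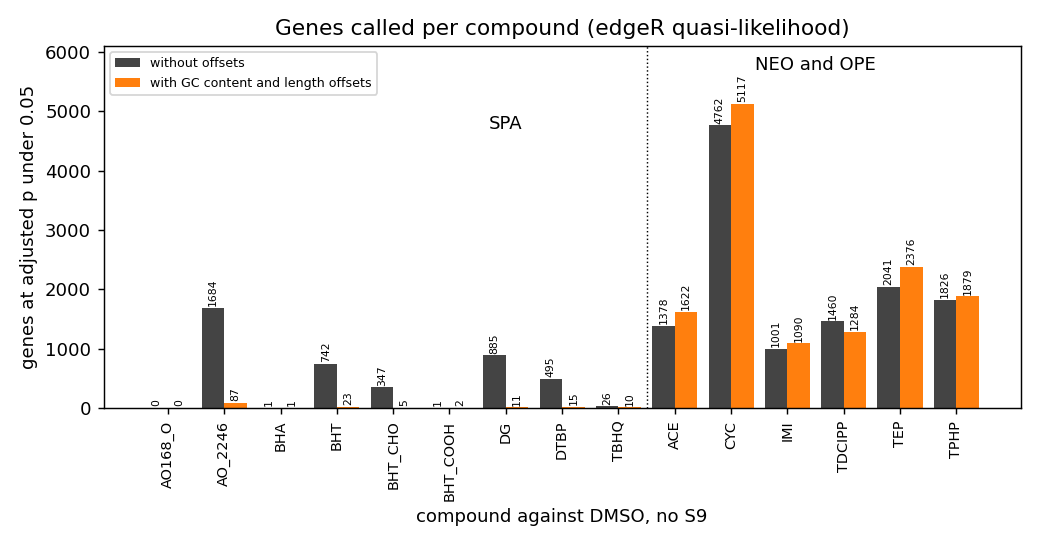
Number of genes changed against DMSO for each of the 15 compounds without S9, with 1 bar without and 1 bar with offsets for GC content and transcript length, and the number of genes at an adjusted p under 0.05 on the vertical axis. CYC had 4762 genes without and 5117 with offsets, and AO_2246 1684 and 87.

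Part of these genes were shared by the 6 compounds. Independent lists of their sizes would share 0.000967 higher and 0.000244 lower genes. The 6 lists are not independent, because they used the same 2 DMSO libraries. In all 6, 348 genes were higher and 195 lower. These counts depended on single libraries, in fits added after the data were seen: they were 14 and 3 without ACE replicate 2, 15 and 2 without IMI replicate 2, 28 and 0 without TDCIPP replicate 2, 28 and 10 without DMSO replicate 1, 41 and 15 without TPHP replicate 1 and 116 and 31 without TEP replicate 1, against 297 to 407 and 127 to 231 without any 1 of the other 8. In fits of only the groups compared they were 21 and 8, and against the mean of the other 14 compounds 134 and 15. Median correlation of the log2 fold changes between pairs of the 6 was 0.911 across 13430 genes, against 0.503 between simulated unchanged groups that share the DMSO libraries. The covariance was 0.215 against a simulated 0.026. Between SPA compounds the correlation was 0.672 against a simulated 0.496 and the covariance 0.0457 against 0.0255, and between a SPA and a NEO or OPE compound the covariance was 0.0155 against 0.0257. Because the 2 DMSO libraries could not be divided, part of the excess may come from the shared controls. The simulated groups also lacked trends over many genes, such as one with GC content, so the part of such trends is not known. Of the genes changed in all 6, 51 were also changed in the same direction in any SPA compound.

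Pairs of related compounds were compared to ask whether exposures within a family differed. CYC against IMI had 10 genes (4 higher, 6 lower), among them TAGLN3 (2.17 ± 0.605 against 0.358 ± 0.221 CPM; log2 fold change 2.58, SE 0.46, adjusted p 0.0401), BOC (1.37, SE 0.25) and CHN2 (1.32, SE 0.26) higher in CYC and TNFSF9 (-1.30, SE 0.25), GABRD (-1.56, SE 0.31) and SOX8 (-1.03, SE 0.21) lower. At an unadjusted p under 0.05 there were 2612, by DESeq2 233 and in a fit of only these groups 608. The 10 dropped to 0 without CYC replicate 1, without IMI replicate 1 or without the DMSO_S9 libraries and DG replicate 1, and to 4 without CYC replicate 2. CYC against ACE and IMI against ACE had 0 genes by edgeR, with 1388 and 498 at an unadjusted p under 0.05 and 0 by DESeq2. Among the OPE compounds, TPHP against TDCIPP, TEP against TDCIPP and TEP against TPHP had 0 genes by edgeR, 183, 636 and 279 at an unadjusted p under 0.05, and 0, 1 and 1 by DESeq2. The 95% interval of the log2 fold change lay within -1 to 1 for 87% of expressed genes in CYC against IMI, 89.9% in CYC against ACE, 93.5% in IMI against ACE and 93.2% to 94.7% in the OPE pairs. Such shares do not show that exposures acted alike. In ACE against DMSO, 1378 of 16113 genes changed, but 466 changed at least 2-fold.

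For the SPA compounds, the question was whether antioxidants and their metabolites changed day 8 cells. The clearest single gene was PRRG3, a membrane protein, which went from 16.6 ± 3.95 CPM in DMSO to 33.7 ± 4.92 CPM in AO_2246 and 35.2 ± 2.37 CPM in DG (log2 fold change 1.11, SE 0.14, adjusted p 0.000331). It rose in 8 of the 9, by 0.93 to 1.11 on the log2 scale, and in 10 of all 15 compounds, so its rise was not confined to the SPA family. It was the 1 gene changed in BHA and in BHT_COOH, and did not pass in AO168_O (0.26, adjusted p 0.901). IRX1, a homeobox gene, rose in BHT (log2 fold change 1.12, SE 0.27, adjusted p 0.019), DTBP, DG, BHT_CHO and AO_2246. NINJ1 rose in 6 SPA compounds by 0.44 to 0.56 on the log2 scale and in 12 of all 15 compounds, the most of any gene. The proliferation gene TOP2A fell in AO_2246, BHT, BHT_CHO, DG and DTBP by 0.50 to 0.64 on the log2 scale, and PHF6 fell in the same 5, most in DG (-0.77, SE 0.13, adjusted p 0.00526). Further genes by rank were TMEM176B (log2 fold change 1.36) and FUT9 (-1.10) in AO_2246, AMN (1.30 in DG, 1.11 in BHT), CRYBG3 in BHT (lower, adjusted p 0.0128), MAFA (1.05), DRD4 and TLDC2 in BHT_CHO, IMPG2 in DTBP (2.12) and HAS2, lower in BHT_CHO (-1.38) and DG (-1.08). Without DMSO replicate 1, IRX1, NINJ1, TOP2A, PHF6 and all genes of this last group lost their calls. The calls of IRX1 in BHT, BHT_CHO, DG and DTBP, TLDC2 in BHT_CHO and IMPG2 in DTBP were lost without any 1 of the 4 libraries, and the other calls of these genes also without at least 1 library of the compound. With offsets for GC content and transcript length, IRX1, TOP2A and PHF6 lost theirs in all 5 compounds, for example TOP2A in BHT at -0.32 (adjusted p 0.36), and NINJ1 in BHT_CHO (0.27) and DG (0.27).

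Of the 24 NRF2 targets, which phenolic antioxidants such as TBHQ can induce, 3 rose in AO_2246, 3 in DTBP, 2 in BHT and 1 in BHT_CHO, and 1 fell in DG. FTH1 and FTL, the ferritin chains, made up most of these, with log2 fold changes of 0.45 (SE 0.10) and 0.51 (SE 0.11) in BHT. All their calls were lost without DMSO replicate 1, and those of FTL in AO_2246 and FTH1 in BHT_CHO without any 1 of the 4 libraries. NQO1 and HMOX1 passed in none of the 9 by edgeR, with NQO1 at 0.35 in TBHQ (SE 0.18, adjusted p 0.533). As a list, the NRF2 targets did not pass (camera adjusted p 0.0677 in DTBP and 0.138 in BHT). List calls in SPA compounds were few: surface ectoderm (camera adjusted p 0.0156, adjusted p = 0.905 with an estimated correlation) and cholesterol synthesis in BHA (0.0227, adjusted p = 0.858 with an estimated correlation), cell cycle in DG (0.0275, adjusted p = 0.996 with an estimated correlation), pluripotency (0.0056, adjusted p = 0.949 with an estimated correlation) and p53 targets in DTBP (0.0279, adjusted p = 0.865 with an estimated correlation) and ATF4 and ER stress genes in TBHQ (0.0417, adjusted p = 0.996 with an estimated correlation). In BHA no gene of these lists passed on its own, and in DG 1 cell cycle gene rose and 2 fell, or 1 and 5 adjusted over the list alone.

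Counts of changed genes were 1684 in AO_2246 (934 higher, 750 lower), 885 in DG (316 and 569), 742 in BHT (476 and 266), 495 in DTBP (367 and 128), 347 in BHT_CHO (216 and 131), 26 in TBHQ (26 and 0), 1 each in BHA and BHT_COOH and 0 in AO168_O by edgeR, where 918 genes had an unadjusted p under 0.05 and DESeq2 gave 0. Few changes reached 2-fold: 22, 47, 11, 4, 7 and 0 in the order from AO_2246 to TBHQ. The log2 fold changes followed GC content across genes, with a Spearman rho of 0.329 to 0.609 in the 9 SPA compounds and -0.053 to 0.223 in the 6 others. With offsets for GC content and transcript length, the counts were 87 in AO_2246, 11 in DG, 23 in BHT, 15 in DTBP, 5 in BHT_CHO, 10 in TBHQ, 2 in BHT_COOH and 1 in BHA. PRRG3 still passed there in all 8 compounds where it had risen, and IRX1 in BHT did not (0.76, adjusted p 0.299). Without DMSO replicate 1, PRRG3 passed in AO_2246 (0.80, adjusted p 0.0445) and in no other SPA compound (0.70 to 0.87), and it was also lost without BHT_CHO replicate 2 in BHT_CHO. Without DMSO replicate 1 the counts were 49 in AO_2246 and 0 in BHT, BHT_CHO, DG, DTBP, TBHQ, BHA and BHT_COOH. Without DMSO replicate 2 they were 1468 in DG, 696 in BHT_CHO, 880 in DTBP, 150 in TBHQ, 96 in BHA, 152 in BHT_COOH and 3 in AO168_O. Leaving out the compound's own replicate 1 or 2 gave 1 and 3038 in AO_2246, 2 and 1229 in BHT, 1 and 4 in BHT_CHO, 2 and 170 in DTBP and 1 and 53 in TBHQ. In DG, the count was 1 without replicate 1, a library with 17992 genes detected where the other DG library had 17274 and the highest of all others 17389. In BHA and BHT_COOH it was 0 without either replicate. The authors' deposited table gave 15 genes for AO_2246, 29 for BHT, 30 for BHT_CHO, 72 for DG, 93 for DTBP and 4 each for AO168_O, BHA and BHT_COOH.

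BHT was compared with its aldehyde and acid forms and BHA with TBHQ. By edgeR, BHT_CHO against BHT, BHT_COOH against BHT, BHT_COOH against BHT_CHO and TBHQ against BHA had 0 genes each, with 157, 812, 560 and 419 at an unadjusted p under 0.05 and 0, 0, 0 and 1 by DESeq2. In these pairs 92.9% to 94.9% of expressed genes had a 95% interval within -1 to 1 on the log2 scale, which does not show that the exposures acted alike.

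The S9 comparisons asked whether S9 changed the cells over the 7 treatments given with and without it. In the 6 compounds, an effect of S9 itself cannot be told apart from a lessened effect of the compound. A batch of the groups without S9 cannot be told apart either. In DMSO, the libraries with S9 stood apart from all others, as given below. Genes of surface ectoderm and amnion were among those that fell with S9: GATA3 by 2.40 (SE 0.24, adjusted p 9.82e-07), HAND1 by 3.92 (SE 0.49, adjusted p 6.49e-06), BAMBI by 2.18 (SE 0.23) and KRT8 by 0.97 (SE 0.14) on the log2 scale. In CYC, GATA3 was at 466 ± 35.5 CPM without S9 and 74.8 ± 39.6 CPM with it. EYA2 (-1.60), GATA2 (-1.29), RAMP1 (-2.34), SLC19A3 (-1.13, SE 0.10, adjusted p 7.22e-07), JCAD, GATA5 and RASGRF2 fell too. Neural genes rose, with SIX3 at 1.05 (SE 0.19), ZIC1 at 1.34 (SE 0.27), STMN2 at 1.05 (SE 0.26) and SOX2 at 0.69 (SE 0.10). RNASE1 (1.47, SE 0.16, adjusted p 1.59e-06), THBS2, FJX1 and BTBD17 led the genes that rose by the naming rule. That rule kept only genes that moved the same way in all 7 treatments, DMSO included. Of 15 surface ectoderm genes, 13 fell (camera adjusted p 3.32e-12, adjusted p = 0.586 with an estimated correlation), of 14 BMP and TGF-beta targets 11 fell (2.42e-12, adjusted p = 0.518 with an estimated correlation), of 12 amnion and trophoblast genes 9 fell and 1 rose (0.000274, adjusted p = 0.586 with an estimated correlation), and of 22 neural ectoderm genes 14 rose and 1 fell (2.49e-06, adjusted p = 0.747 with an estimated correlation). In total 4504 of 15982 genes changed, 2104 higher and 2400 lower, and the count lay between 3882 and 5322 when a library was left out. NANOG (0.32, adjusted p 0.487) and POU5F1 (-0.02, adjusted p 0.969) did not pass over the 7 treatments. In the 6 compounds alone, without DMSO and DMSO_S9, an analysis added after the data were seen, 7864 genes changed, NANOG rose by 0.75 (SE 0.113, adjusted p 1.6e-05) and POU5F1 by 0.39 (SE 0.0665, adjusted p 6.15e-05), and GATA3 fell by 2.53 (SE 0.244).

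DMSO_S9 against DMSO was then compared with the effect of S9 in the other 6 treatments. A foreign or mislabelled culture was not excluded for the DMSO_S9 libraries. The changes below therefore cannot be read as an effect of S9. Of 7356 genes changed in DMSO_S9 and tested in both, 1050 changed the same way with S9 in the 6 treatments and 2982 the opposite way. POU5F1 fell from 698 ± 246 CPM in DMSO to 55 ± 0.14 CPM in DMSO_S9 (log2 fold change -3.66, SE 0.42, adjusted p 1.28e-07), and NANOG fell by 3.86 (SE 0.43). NLRP2 went from 99.2 ± 2.27 to 0.201 ± 0.0655 CPM (-8.89, SE 0.20, adjusted p 2e-23), and NNAT, an imprinted gene, from 8.53 ± 0.566 to 494 ± 27.2 CPM (5.86, SE 0.37). ZNF248 (5.93), ZNF680 (6.99), TYW3 (7.50) and KIF25 (5.45) were further genes at low CPM in DMSO and higher in DMSO_S9, and TCEAL2 (-5.88), ZNF681 (-4.31), ERVH48-1, ZNF560, ALPG (-6.19), CASP8 and ZNF667 were lower. Glycolysis genes rose, such as LDHA by 2.13 (SE 0.29) and SLC2A1 by 1.75 (SE 0.18), as did the neural gene PAX6 (2.29), though PAX6 did not pass with any 1 of the 4 libraries left out (2.00 to 2.62). Of 18 pluripotency genes, 15 fell (camera adjusted p 4.26e-10, adjusted p = 0.644 with an estimated correlation), of 20 cell cycle genes 17 fell and 1 rose (3.07e-06, adjusted p = 0.747 with an estimated correlation), and of 18 hypoxia and glycolysis genes 10 rose and 1 fell (0.000606, adjusted p = 0.586 with an estimated correlation). Metallothioneins fell for 6 of 7 genes (0.00244, adjusted p = 0.817 with an estimated correlation) and ATF4 and ER stress genes for 13 of 19 (0.00625, adjusted p = 0.996 with an estimated correlation). In total 7369 genes changed, 3385 higher and 3984 lower, 2560 of them at least 2-fold, and 4538 without DMSO replicate 1. The Spearman correlation of the DMSO_S9 libraries with each other was 0.997 across genes, and their highest with a library of another group 0.962, where the libraries of every other day 8 group reached 0.992 to 0.998.

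Each compound with S9 was compared with DMSO_S9, and these comparisons carried the difference of DMSO_S9 from all other groups. NLRP2 was higher by 8.96 to 9.07 on the log2 scale in the 6 compounds (SE 0.20 each) and NNAT lower, at -5.87 in ACE_S9 to -6.52 in CYC_S9. Also higher in all 6 were ERVH48-1 and ZNF560, and IGSF1 was lower in all 6. Changed genes numbered 7816 in ACE_S9, 8114 in CYC_S9, 7976 in IMI_S9, 8153 in TDCIPP_S9, 8153 in TEP_S9 and 8125 in TPHP_S9. Against DMSO without S9, a reference added after the data were seen, the same groups had 62, 137, 111, 559, 180 and 362 genes, and GATA3 passed in none of them by edgeR (log2 fold changes 0.64 to 1.78, adjusted p 0.116 to 0.644). In the interactions of compound and S9, NLRP2 was at 8.96 to 9.22 (SE 0.24), TCEAL2 and ZNF681 were higher and PXDN and DNAJC15 lower in all 6. Interactions passed for 5809 genes in ACE, 7374 in CYC, 5213 in IMI, 5527 in TDCIPP, 5633 in TEP and 5417 in TPHP (3485 without TPHP replicate 1). Against the S9 shift of the other 5 compounds, 0 genes passed by edgeR for any of the 6.

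A score of surface ectoderm genes minus neural ectoderm genes put the groups on 1 scale. It was 0.776 ± 0.199 in DMSO, 2.66 ± 0.667 in TDCIPP to 3.78 ± 0.0121 in CYC among the 6 NEO and OPE compounds, and 0.37 to 0.849 in the 9 SPA compounds. The 6 exceeded the 9 by 2.41 on average (2-sided exact permutation test of group means, p = 2e-04, the smallest that 5005 arrangements can give). With S9, the same 6 compounds scored 1.32 to 1.88, lower by 1.51 on average and lower in 6 of 6 (2-sided exact permutation of signs, p = 0.0312, the smallest that 64 arrangements can give). D0 scored 1.76 and DMSO_S9 -0.0662. The D0 value lay above DMSO because its neural ectoderm mean was low (2.57 and 2.52, against 4.71 and 5.04 in DMSO). Its surface ectoderm mean was also lower than in DMSO (4.24 and 4.36, against 5.63 and 5.67). The score thus compares the 2 lists and does not measure surface ectoderm alone. Between compounds of a family the 95% interval of the score difference included 0 in all 10 pairs, the widest difference being CYC minus IMI at 0.936 (-0.0892 to 1.96), with BHT_CHO minus BHT at -0.282 (-1.31 to 0.743) and TEP minus TDCIPP at 0.666 (-0.36 to 1.69).

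**Figure D3:**
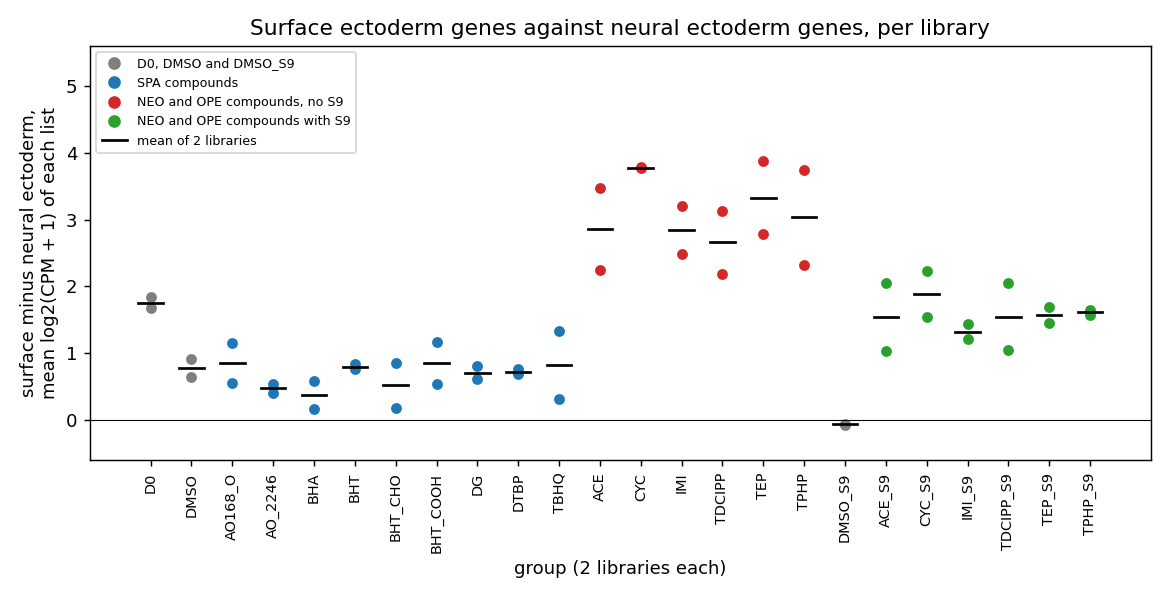
Ectoderm score of each library, the mean log2(CPM + 1) of surface ectoderm genes minus that of neural ectoderm genes, with groups along the horizontal axis, 1 point per library and 2 libraries per group. The 6 NEO and OPE groups lay at 2.66 to 3.78, the same compounds with S9 at 1.32 to 1.88 and the SPA groups at 0.37 to 0.849.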

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

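The tests for a foreign culture, for S9 in the medium, for a response to the antioxidants and for GC content and transcript length in both families were chosen only after their results had been seen. The other tests were written before their results were seen. The interaction of compound and S9 marked 6 results as differences between groups, tested as such: 5809 genes in ACE, 7374 in CYC, 5213 in IMI, 5527 in TDCIPP, 5633 in TEP and 5417 in TPHP. All 6 use the DMSO_S9 libraries. With the S9 shift of the other 5 compounds as reference, 0 genes passed by edgeR in each of the 6.

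Both DMSO_S9 libraries stood apart from all other day 8 libraries: 95 genes, among them NLRP2 and NNAT, lay at least 4-fold beyond all 46 other libraries, where the other day 8 groups had 0 such genes and D0 had 144. That limit was set after a first one, 0.1 against 1 CPM, had given 4 genes. S9 in the medium, acting alike in every treatment, can be excluded as the cause: over all 7356 genes changed in DMSO_S9 against DMSO, the median shift in that direction was 0.72, against -0.0844 with S9 in the other 6 treatments (quartiles -0.252 to 0.0471) and -0.0233 in those treatments with S9 against DMSO (-0.204 to 0.14). A foreign or mislabelled culture could account for the 95 genes and stays open, as does an effect of S9 with solvent alone, for which no test was made. Every comparison with DMSO_S9 in the report carries this doubt.

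Fold changes of the SPA compounds against DMSO followed GC content (rho 0.329 to 0.609), and offsets for GC content and transcript length left 154 calls of 4181 over the 9 compounds, so differences between libraries in GC content and length could account for most of them. Of the 4181 calls, 129 were made with and without the offsets (3.08%), which meets the bound of 1 in 10 set against a response to the antioxidants. That bound was wrong, because the offsets also take out any response that follows GC content, so a response cannot be told apart from the GC trend here. A single DMSO library out of place also stays open: the difference of the DMSO libraries followed GC content with a rho of -0.3, at the limit of 0.3 that had been set. DMSO replicate 1 had the lowest rho with GC content of the 46 day 8 libraries (-0.444, against -0.211 in replicate 2), and without it 7 of the 8 SPA counts above 0 fell to 0, while the replicate differences of D0 (-0.655), AO_2246 (0.407) and TDCIPP (-0.365) were larger.

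The 6 NEO and OPE compounds without S9 shared higher GATA3 and HAND1 and lower ZIC1. Chance values of the shared DMSO libraries can be excluded as the whole cause, because the ectoderm score of the 6 groups exceeded that of the 9 SPA groups without use of DMSO (2-sided exact permutation, p = 2e-04). GC content and transcript length can be excluded as well, since the offsets left 13368 calls where there had been 12468, with 10875 in both. A culture or library batch shared by the 6 groups cannot be told apart from the compounds: the labels give no batch, and the score was higher without S9 than with it in 6 of 6 compounds, which either would give. An effect of the compounds that S9 lessens stays open as a hypothesis beside it.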

How the results depend on the processing

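The GC content and length offsets, the removal of DMSO_S9 and DG_1, the reference DMSO without S9, the S9 shift of the other 5 compounds and the S9 fit of 6 treatments were chosen after seeing the data, as was leaving out 1 library for the genes changed in all 6 NEO and OPE compounds (17 to 636 genes, against 543). Counts of changed genes stayed within 1.5 times for 39 of 40 comparisons with RLE scaling, 36 of 40 with no filter on low counts, 30 of 40 with DESeq2, 31 of 40 with the offsets, 37 of 41 with a replicate block, 26 of 39 in fits of only the groups compared and 22 of 25 without DMSO_S9 and DG_1. Where a count moved or a sign turned, the cause was not tested. The lone library left in a group by leaving out the other was assumed to vary like the other groups. Depth of 17918867 to 20096130 counts and 2 libraries per group limit small changes and genes near 1 CPM.

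DESeq2 gave 1270 genes in BHT, 931 in BHT_CHO, 21 in BHT_COOH, 1408 in DG, 1000 in DTBP, 139 in TBHQ, 233 in CYC against IMI, and 1 each in TBHQ against BHA, TEP against TDCIPP and TEP against TPHP. RLE scaling gave 17 in TBHQ. With no filter on low counts there were 158 in BHT_CHO, 302 in DTBP, 7 in TBHQ and 4 in CYC against IMI. With the GC content and length offsets there were 87 in AO_2246, 23 in BHT, 5 in BHT_CHO, 2 in BHT_COOH, 11 in DG, 15 in DTBP, 10 in TBHQ, 24 in CYC against IMI and 1 in TEP against TPHP. Without DMSO_S9 and DG_1 there were 185 in BHT_CHO, 9 in TBHQ and 0 in CYC against IMI. Fits of only the groups compared gave 7 in AO_2246, 1 in BHT, 183 in ACE, 756 in TDCIPP, 514 in TEP, 43 in TPHP, 608 in CYC against IMI and 0 in BHA, BHT_CHO, BHT_COOH, DG, DTBP and TBHQ. Against the mean of the other 14 compounds there were 1 in AO168_O, 105 in BHA, 0 in BHT_COOH, 129 in DTBP, 11 in TBHQ, 3389 in ACE, 615 in IMI, 283 in TDCIPP and 868 in TPHP.

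The replicate numbers showed no pairing common to all groups (276 pairs of groups, correlation -0.556 to 0.695, median -0.0135). The correlation was above 0.1 in 88 pairs and below -0.1 in 66. The neural ectoderm mean was lower in replicate 1 than in replicate 2 in DMSO and every SPA group. Among the NEO and OPE groups without S9, it was lower in TEP and TPHP and higher in ACE, CYC, IMI and TDCIPP. A pairing within part of the groups stays open, and 1 block over all libraries cannot model it. The replicate block gave 526 genes in BHT_CHO, 2 in BHT_COOH and 1 each in TEP against TDCIPP and TEP against TPHP, and 109 list calls where there were 102. List calls were 1 with a correlation estimated per list and 157 with fry.

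With DMSO without S9 as reference there were 62 genes in ACE_S9, 137 in CYC_S9, 111 in IMI_S9, 559 in TDCIPP_S9, 180 in TEP_S9 and 362 in TPHP_S9. Against the mean of the other 5 compounds with S9 there were 0 in each of the 6, as there were for interactions with the S9 shift of the other 5. S9 in 6 treatments without DMSO and DMSO_S9 gave 7864 genes.

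Leaving out 1 library at a time gave 7971 to 8735 genes in DMSO against D0, 0 to 3 in AO168_O, 1 to 3038 in AO_2246, 0 to 96 in BHA, 0 to 1229 in BHT, 0 to 696 in BHT_CHO, 0 to 152 in BHT_COOH, 0 to 1468 in DG, 0 to 880 in DTBP and 0 to 150 in TBHQ. It gave 18 to 1736 in ACE, 2398 to 4248 in CYC, 19 to 928 in IMI, 34 to 1570 in TDCIPP, 206 to 2463 in TEP and 79 to 2232 in TPHP. Against DMSO_S9 it gave 6078 to 6195 in ACE_S9, 6316 to 6612 in CYC_S9, 6235 to 6337 in IMI_S9, 6355 to 6648 in TDCIPP_S9, 6342 to 6580 in TEP_S9 and 6380 to 6446 in TPHP_S9. DMSO_S9 against DMSO had 4538 to 6783 and S9 across 7 treatments 3882 to 5322. Interactions had 4134 to 5616 in ACE, 5837 to 7245 in CYC, 3560 to 5183 in IMI, 3692 to 5462 in TDCIPP, 3922 to 5639 in TEP and 3485 to 5479 in TPHP. CYC against IMI had 0 to 7, TEP against TDCIPP 0 to 2, TEP against TPHP 0 to 3 and the other pairs 0 to 0.

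Results per gene were counted as the same also where a gene passed neither in the main fit nor in the alternative. By this count, 2374 of 2752 stayed the same with 1 library left out, 451 of 478 with DESeq2, 426 of 478 with the offsets and 475 of 478 with the replicate block. In fits of only the groups compared it was 346 of 449, and against the mean of the other 14 compounds 204 of 277. It was 5 of 48 against DMSO without S9, 0 of 48 against the mean of the other 5 compounds with S9 and 0 of 36 against the S9 shift of the other 5. These counts pool all comparisons. They do not give the stability of compounds against DMSO, where many calls were lost with 1 library left out, as given above. For genes that passed in the main fit, signs turned under other references alone. POU5F1 did not pass there, and its sign also turned with 1 library left out in ACE (-0.61 to 0.12), IMI (-0.51 to 0.22), TDCIPP (-0.63 to 0.11), TEP (-0.46 to 0.28), TPHP (-0.59 to 0.15) and S9 across 7 treatments (-0.0804 to 0.18). With S9 in 6 treatments it was 0.39 (adjusted p 6.15e-05), against -0.0193 in 7. The passing genes whose sign turned against the mean of the other 14 compounds were IRX1 in AO_2246 (-0.00392), STRA6 in AO_2246 (-0.032) and BHT (-0.0132), NINJ1 in BHT_CHO (-0.0222) and DG (-0.00783) and PHF6 in DTBP (0.0238). Against DMSO without S9 they were ZNF681 in ACE_S9 (-0.0244), IMI_S9 (-0.0366) and TEP_S9 (-0.00145), ZNF248 in ACE_S9 (0.67), CYC_S9 (0.31), IMI_S9 (0.32), TEP_S9 (0.31) and TPHP_S9 (0.21) and TCEAL2 in TDCIPP_S9 (-0.30). Against the mean of the other 5 compounds with S9 they were NLRP2 in ACE_S9 (-0.0336), TDCIPP_S9 (-0.053) and TPHP_S9 (-0.0559), ERVH48-1 in ACE_S9 (-0.0706), TDCIPP_S9 (-0.0966) and TPHP_S9 (-0.0153), ZNF681 in ACE_S9 (-0.0131) and IMI_S9 (-0.0276), NNAT in ACE_S9 (0.30), IMI_S9 (0.22), TDCIPP_S9 (0.0189) and TPHP_S9 (0.18), SBF2 in ACE_S9 (0.0438), IMI_S9 (0.0842) and TEP_S9 (0.00406), ZNF248 in ACE_S9 (0.34), IGSF1 in IMI_S9 (0.0343) and TEP_S9 (0.15) and ZNF560 in TEP_S9 (-0.16) and TPHP_S9 (-0.11). For interactions against the S9 shift of the other 5 compounds they were TCEAL2 in ACE (-0.0481), IMI (-0.20) and TPHP (-0.0221), PXDN in ACE (0.0181), IMI (0.0763) and TEP (0.10), NNAT in ACE (0.0922) and IMI (0.22), NLRP2 in IMI (-0.0534), TDCIPP (-0.063), TEP (-0.0678) and TPHP (-0.0633), DNAJC15 in TDCIPP (0.0579) and TEP (0.14) and ZNF681 in TEP (-0.0646).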

Other observations

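The count of splits for S9 was written before its result was seen, and the genes standing apart by group were counted after the data had been seen. For S9 across the 7 treatments, the real division gave 4504 genes and the highest of the others 4971. Of 100 divisions, 2 gave as many, the real one included. The others moved single libraries and mostly separated the 2 libraries of a group, which can lower a count by itself. A chance difference between groups therefore cannot be excluded by this test. In the division with 4971 genes, DMSO and DMSO_S9 had changed sides while 4 of the other 6 treatments stayed in place. Why it gave more genes than the real division was not tested.

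Across the 15 compounds without S9, 9335 genes changed in none. COL9A3, ZNF513 and FBXW5 were higher in 11 compounds, and ATP6V1A and PHF6 lower in 10. All 15 comparisons used the same 2 DMSO libraries.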
